A study of Mus musculus with 8 samples.

How the data were processed

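Poly(A) RNA was measured by sequencing in primary mouse hippocampal neurons taken at embryonic day 19 and kept in culture. Per the labels, neurons were infected with lentivirus carrying a scrambled hairpin or a hairpin against CNOT7 at 13 to 15 days in vitro and harvested at 17 to 19 days in vitro. RNA was bound to poly(U) agarose. Total poly(A) RNA was eluted at 75 °C. For the long-tail fraction, a wash at 50 °C, which the labels describe as removing tails under 50 nucleotides, came before the elution at 75 °C. The 8 libraries formed 4 groups of 2 libraries each: scrambled total, scrambled long tails, knockdown total and knockdown long tails. Libraries were made with the Nextflex qRNA-Seq Kit, and whether its molecular indexes were used is not given in the sources used here. The labels do not say whether the 2 libraries of a group came from separate cultures, so a p-value for a single gene measures only the spread between these samples.

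Per the submitters' processing notes, CASAVA, TopHat2, RSEM, DESeq and DESeq2 and the mm10 build were used; versions and the role of each tool are not given in the sources used here. The deposited gene table holds 23845 genes and, per its name and values, gives TPM, a score of relative transcript abundance from RSEM scaled to 1000000 per library, that the authors rounded to whole numbers. Column sums ran from 999689 to 999809. TPM is a share within each library, so a difference between fractions is a difference in shares and not in tail length or in amount of RNA. Read counts and depths were not analysed here, so the depth behind each value is unknown and no counting intervals were made. The authors' 2 deposited result tables, 1 for total RNA and 1 for long tails, give per the file headers a log2 fold change, a p-value and an adjusted p-value, and hold only genes with an adjusted p under 0.05. Their deposited mean of normalized counts was the same number for a gene in both tables, so 1 normalization lay behind both. The deposited log2 fold change had the opposite sign to the knockdown minus scrambled difference in TPM for all 201 entries, and it was turned so that positive values mean higher in knockdown. In the gene table, names of 27 genes stood as dates, and these entries could not be matched to a gene.

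Values were taken as log2(TPM + 1) for the 13681 genes with a mean of at least 1 TPM. A single limma model (version 3.58.1, R 4.3.3; lmFit, then eBayes with a mean-variance trend) with 4 group means was fitted to all 8 libraries, and 5 contrasts were tested two-sided: knockdown minus scrambled in total RNA, the same in long tails, long tails minus total in scrambled and in knockdown neurons, and the interaction, which is the knockdown difference in long tails minus that in total RNA. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 per contrast. With 2 libraries against 2, an exact permutation test of a single gene cannot give a p under 0.333, so none was run per gene. Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 26 lists with at least 3 tested members. At this setting camera compares the genes of a list with other genes, nearly as if genes were independent. Its p-values do not measure spread between cultures. The test was repeated with an estimated correlation and with fry of limma.

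The 27 lists were CCR4-NOT deadenylase complex; poly(A) polymerases, poly(A)-binding and CPEB proteins and other tail factors; decapping and mRNA decay; dendritically localised and synaptic plasticity mRNAs; activity-regulated immediate early genes; glutamate receptors; GABA receptors; presynaptic release proteins; voltage-gated channels; RNA transport granule proteins and kinesins; markers of excitatory neurons, inhibitory neurons, astrocytes, the oligodendrocyte lineage, microglia, endothelial and mural cells, and proliferation; cytosolic ribosomal proteins; translation factors; oxidative phosphorylation subunits encoded in the nucleus; transcripts of the mitochondrial genome, which had no entries in the table; replication-dependent histones; interferon-stimulated genes; the unfolded protein response; p53 targets and apoptosis; sterol synthesis; and proteasome subunits. Of 1091 members, 1073 had an entry and 1021 were tested. The lists, tests, contrasts and the first set of other settings were fixed before the data were examined.

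Named genes followed a rule fixed at the same time. It takes Cnot7, up to 10 called genes per direction, the genes with the smallest p up to 5 per direction where fewer than 5 were called (ties in alphabetical order), up to 4 members per list with the smallest p, and 10 genes per direction from each of the authors' tables. Some genes that the rule takes are not reported here. The overlap of the authors' tables was tested with Fisher's exact test (R 4.3.3), two-sided, against the 13681 tested genes. Its p is not given, because the test takes the tables as independent and the fractions may share cultures. Positions and transcript lengths came from GENCODE M21 (GRCm38), which may differ from the annotation the authors used; a length, the median over a gene's transcripts, was found for 13080 tested genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

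Other settings fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 TPM, median scaling, quantile normalization, no variance trend, a fit of only the 4 libraries compared, a block for the replicate number over all libraries or within each condition, and leaving out each library in turn. Whole-number rounding gave 204 tested genes the same value in both libraries of every group, at means of at most 8 TPM. Filters at a mean of 10, 20 and 50 TPM, their forms with median scaling or with the block, and a table without the ribosomal RNA precursor Rn45s were tried only after this had been seen. The procedure was tested on simulated data with 200 changed genes per run over 20 runs for the total contrast. The planned filter found 22.1% of 2-fold and 96.2% of 4-fold changes, with 1.1 false calls per run on average. At a mean of 20 TPM it found 91.52% of 2-fold changes. The simulated noise was independent between genes and libraries, with a spread smoothed over expression level and no deviating library. These shares therefore do not give the power in the real libraries.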

Results

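CNOT7 is a deadenylase, an enzyme of the CCR4-NOT complex that shortens the poly(A) tails of mRNAs. Its mRNA was targeted with a hairpin in cultured mouse hippocampal neurons, and poly(A) RNA was sequenced either whole or after a wash that left long tails, in 4 groups of 2 libraries each. The comparisons ask which mRNAs differed after knockdown. They also ask whether an mRNA's share of the long-tail library, relative to its share of the total library, differed with knockdown. Levels below are mean TPM ± SD, n = 2 libraries per group. The deposited TPM summed to between 999689 and 999809 per library, and the read depth is unknown. The ribosomal RNA precursor Rn45s took from 2.898% of TPM in knockdown long-tail library 2 to 18.559% in knockdown long-tail library 1. Knockdown long-tail library 2 stood apart from the other 7 on the main axis of variation (50.1% of variance, position 56.6), and the 2 knockdown long-tail libraries correlated across genes at r = 0.966, below the 0.982 to 0.985 of the other groups.

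Cnot7 itself (chromosome 8, 40492540 to 40515847, minus strand, GRCm38) was at 39 ± 4.24 TPM in scrambled and 14 ± 2.83 TPM in knockdown total RNA. In long tails it was at 29.5 ± 2.12 and 10 ± 1.41 TPM. The difference was −1.42 on the log2 scale in total RNA and −1.48 in long tails (SE 0.187 in each), with no overlap between libraries. In the authors' deposited table Cnot7 fell by 1.12 on the log2 scale in total RNA (adjusted p = 3.96e-05) and by 1.18 in long tails (adjusted p = 1.02e-05). In the limma model over all genes it missed the threshold in total RNA (adjusted p = 0.153), with a range of 2.28e-07 to 0.512 over the alternatives. Its partner Cnot6l was at 16 ± 2.83 TPM in scrambled and 10 ± 2.83 TPM in knockdown total RNA, and its close relative Cnot8 at 63.5 ± 0.707 and 52.5 ± 9.19 TPM. Of 17 tested members of the CCR4-NOT complex and its TOB/BTG partners, 3 were higher and 14 lower in total RNA. The list median of −0.07 was that of all genes, with 8 of 17 members above it. When adjusted over the list alone 1 member passed (Cnot7). The list was not called by camera (adjusted p = 0.194, and 0.973 with an estimated correlation).

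**Figure D1:**
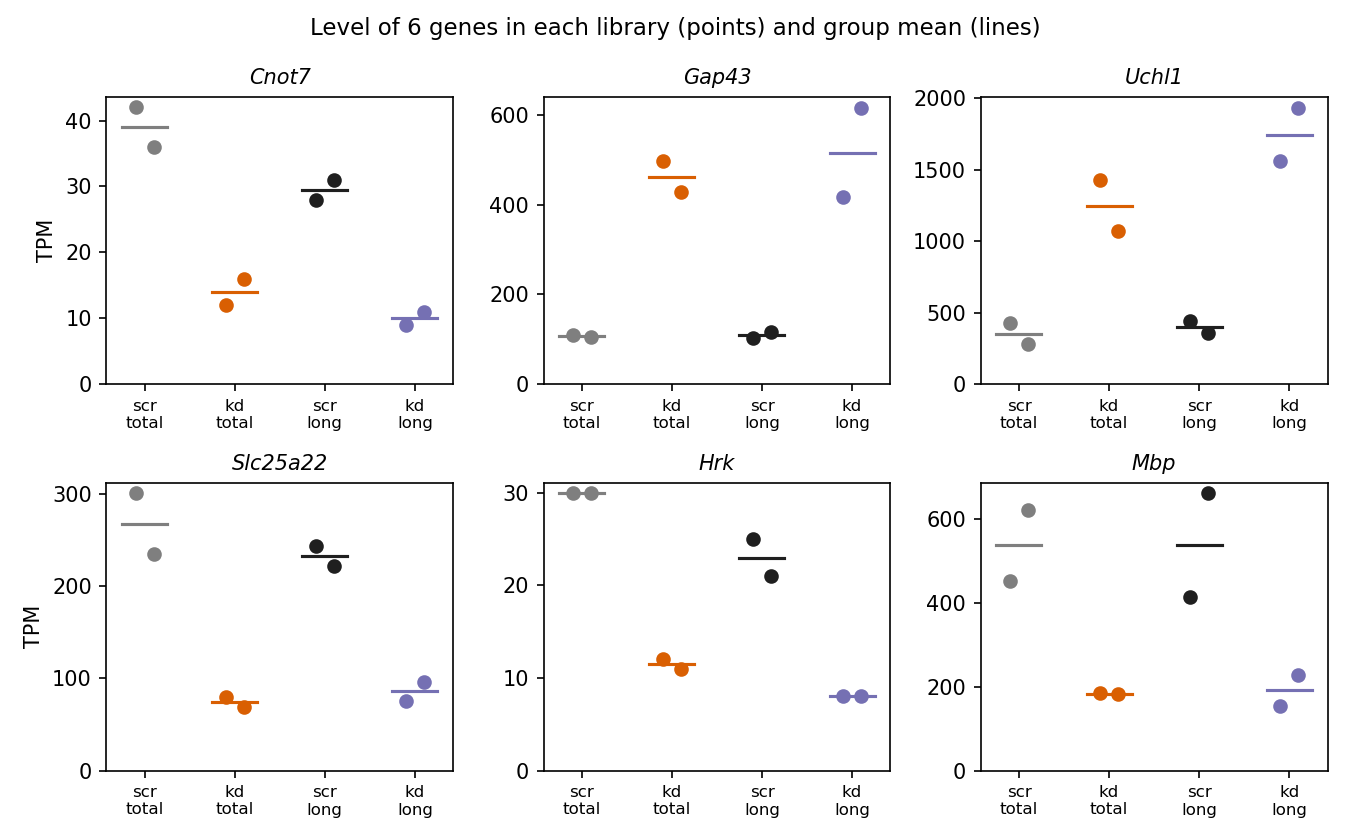
TPM (vertical axes) of 6 genes in each library (points) of the 4 groups, with the group mean as a line; scr is scrambled, kd is knockdown, and total and long are the fractions. Cnot7 was at 39 TPM in scrambled and 14 TPM in knockdown total RNA, and Gap43 at 107.5 and 461.5 TPM.

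The total poly(A) RNA of knockdown neurons held a larger share of Gap43 and Uchl1 mRNA and a smaller share of Slc25a22 and Hrk mRNA. Gap43, a phosphoprotein of growth cones, was at 107.5 ± 3.54 TPM in scrambled and 461.5 ± 48.8 TPM in knockdown neurons. Uchl1, a ubiquitin hydrolase abundant in neurons, was at 355 ± 103 and 1250 ± 252 TPM. Lower in knockdown were Slc25a22, a mitochondrial glutamate carrier (268 ± 46.7 and 74.5 ± 7.78 TPM), and Hrk, a BH3-only protein that promotes apoptosis (30 ± 0 and 11.5 ± 0.707 TPM). These 4 genes lie on chromosomes 16 (Gap43, 42248442 to 42340651), 5 (Uchl1, 66676091 to 66687234, and Hrk, 118164648 to 118189478) and 7 (Slc25a22, 141429744 to 141437892).

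In the authors' deposited table for total RNA, 104 genes changed, 72 higher and 32 lower in knockdown. Those with the smallest adjusted p among the rises included Gap43 (log2 1.84, adjusted p = 9.75e-18), the kinase-like Cdkl2 (1.47, adjusted p = 3.52e-12), the phosphatase Mtmr7 (1.45, adjusted p = 4.86e-09) and Uchl1 (1.47, adjusted p = 2.56e-08), and after them Fbxl16, Ablim3, Ugcg, Klc1 and Pccb. Those that fell in the authors' deposited table included Slc25a22 (−1.48, adjusted p = 6.56e-11) and Hrk (−1.10, adjusted p = 3.52e-06), and after them Cnot7, Mbp, Cox15, Galnt16, Ahcyl2 and Smap2. The limma model on the rounded TPM called 0 genes in total RNA (smallest adjusted p = 0.0669), while 868 had an unadjusted p under 0.05, 280 higher and 588 lower, where 684.05 were expected by chance. The 10 genes that the rule takes by smallest p, among them Gap43, Cdkl2, Slc25a22 and Hrk, shared that smallest adjusted p. Libraries did not overlap between the groups for 28.82% of genes, against 33.3% by chance for values without ties. Ties between whole-number values lower that chance share, so 28.82% is not shown to be below it. Also at that adjusted p were Ablim3 (6 ± 0 and 16 ± 0 TPM) and 4 genes at 4 TPM or less in every group (Casp1 and Pbld1 higher, 4930513N10Rik and R3hdml lower). The count depended on the filter on low genes: it was 43 without one, 6 at a mean of 5 TPM (Cdkl2, Gap43, Mtmr7 and Slc25a22 among them) and 7 to 10 at means of 10 to 50 TPM, the last 3 filters chosen after the data were seen. With the replicate number as a block at those 3 filters it was 91, 118 and 67, though the labels state no pairing. All 6 genes at 5 TPM and 6 of the 43 without a filter are in the authors' deposited table, whose genes were chosen on these samples and are not independent evidence.

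As groups, camera called 9 of the 26 lists in total RNA, 6 higher and 3 lower. Oligodendrocyte lineage markers were called lower, with 22 of 23 members lower and a median log2 of −0.55 (adjusted p = 1.42e-07; adjusted p = 0.284 with an estimated correlation). Myelin proteins were among them, with Mbp at 537 ± 120 TPM in scrambled and 183.5 ± 2.12 TPM in knockdown, and Cnp at 201.5 ± 4.95 and 124.5 ± 4.95 TPM. By limma, 9 members had an unadjusted p under 0.05, 6 passed when adjusted over the list alone and 0 over all genes, and the authors' deposited table includes Mbp. The median of the list, relative to each gene's mean, was between 0.0838 and 0.508 in the 4 scrambled libraries and between −0.436 and −0.0805 in the 4 knockdown libraries. Astrocyte markers were lower too (26 of 29 members, median −0.26, adjusted p = 0.0236), as were interferon-stimulated genes (41 of 45, median −0.30, adjusted p = 0.00873). Both had an adjusted p of 0.973 with an estimated correlation.

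Sterol synthesis genes were called higher as a group, with 20 of 24 higher and a median of 0.29 (adjusted p = 2.34e-07; adjusted p = 0.973 with an estimated correlation). Hmgcs1, a synthase early in the pathway, was at 416 ± 11.3 TPM in scrambled and 654 ± 15.6 TPM in knockdown. In the authors' deposited table Hmgcs1 rose by 0.68 on the log2 scale (adjusted p = 0.00123). Proteasome subunits (26 of 32 higher, median 0.15, adjusted p = 0.000105) and replication-dependent histones (44 of 53 higher, median 0.54, adjusted p = 3.61e-06) were called upward as well. Dendritically localised mRNAs (median 0.03, adjusted p = 0.00833), translation factors (0.03, adjusted p = 0.0402) and ribosomal proteins (0.02, adjusted p = 0.0479) were called upward with medians close to 0, against a median of −0.07 over all genes. With an estimated correlation each of these 8 lists had an adjusted p of 0.973, and fry called 0 lists. None of the 8 had a member past the threshold when adjusted over the list alone. Leaving out knockdown total library 1 ended the calls of sterol, proteasome, dendritic, interferon, astrocyte, translation and ribosomal lists and left 2 lists. The histone call ended without knockdown total library 2, in which their median was 1.24. The dendritic, interferon and astrocyte calls also ended without scrambled total library 2, and the astrocyte call without knockdown total library 2. The ribosomal and translation calls ended without scrambled total library 1, and the translation call without either knockdown long-tail library. At a mean of 20 TPM the histone, ribosomal and translation calls ended, the last also with quantile normalization. Relative to each gene's mean, sterol medians overlapped between scrambled total (0.146 and −0.199) and knockdown total libraries (0.508 and −0.00762). So did proteasome medians (−0.151 and −0.0302, against 0.129 and −0.101) and those of the dendritic, interferon, ribosomal and translation lists, but not of the astrocyte list. The histone median in knockdown total library 1 (−0.0506) was below both scrambled ones (0.139 and 0.0233).

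Lists that camera did not call in total RNA had these median log2 differences and adjusted p-values. Among neuronal lists, excitatory neuron markers were at 0.00 (adjusted p = 0.0771), inhibitory neuron markers at −0.08 (adjusted p = 0.441), glutamate receptors at −0.04 (adjusted p = 0.366), GABA receptors at 0.00 (adjusted p = 0.167), presynaptic release genes at −0.05 (adjusted p = 0.833), channels at −0.08 (adjusted p = 0.998) and immediate early genes at 0.00 (adjusted p = 0.0598). Among RNA lists, poly(A) factors were at −0.09 (adjusted p = 0.998), decapping and decay genes at −0.09 (adjusted p = 0.833) and granule proteins at 0.03 (adjusted p = 0.0712). Microglia markers were at −0.29 (adjusted p = 0.301), endothelial and mural markers at −0.19 (adjusted p = 0.59) and proliferation genes at −0.01 (adjusted p = 0.59). Oxidative phosphorylation subunits were at −0.11 (adjusted p = 0.441), the unfolded protein response at 0.03 (adjusted p = 0.102) and p53 targets at −0.09 (adjusted p = 0.793). The camera direction was upward for inhibitory markers, glutamate receptors, presynaptic and proliferation genes and for excitatory markers, whose medians were below 0 but above or near that of all genes.

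Among long-tailed RNA, Gap43, Uchl1, Hrk and Slc25a22 differed in the same directions as in total RNA. Gap43 was at 110 ± 9.90 TPM in scrambled and 515.5 ± 141 TPM in knockdown long tails. Uchl1 was at 403 ± 58 and 1747 ± 260 TPM, and Tubb3, a neuronal beta-tubulin, at 289 and 592 TPM. Hrk was at 23 ± 2.83 and 8 ± 0 TPM and Slc25a22 at 233 ± 15.6 and 86 ± 14.1 TPM. In the authors' deposited table for long tails, 97 genes changed, 63 higher and 34 lower. The rises there included Gap43 (log2 1.99, adjusted p = 4.82e-21), Uchl1 (1.76, adjusted p = 2.39e-12) and Fbxl16 (1.46, adjusted p = 2.38e-08), then Cdkl2, Prkag2, Enoph1, Tubb3, Ablim3 and Klc1. The falls in the authors' deposited table included Hrk (−1.28, adjusted p = 1.68e-08), then Ahcyl2, Slc25a22, Fstl5, Cnot7, Shisa6, Mbp, Tmem30a and Cox15. The limma model called 0 genes in long tails (smallest adjusted p = 0.0593, for Pbld1 at 1.00 and 4 TPM), with 1193 at an unadjusted p under 0.05, 308 higher and 885 lower. Libraries did not overlap for 26.03% of genes, against 33.3% by chance for values without ties, a share that ties lower. The next genes by the rule, at an adjusted p of 0.152, included Ablim3, Ecscr and Gap43 upward and Ddc, Hrk, R3hdml and Rab9b downward. The count was 54 without a filter, 5 at a mean of 5 TPM (Gap43, Hrk and Uchl1 among them) and 11 to 13 at means of 10 to 50 TPM. With the replicate number as a block it was 121, 297 and 109 at means of 10, 20 and 50 TPM. All 5 genes at 5 TPM and 6 of the 54 without a filter are in the authors' deposited table, which is not independent evidence.

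Of the 26 lists camera called 7 in long tails, 6 higher and 1 lower. Oligodendrocyte lineage markers again were lower in 22 of 23 members (median −0.48, adjusted p = 4.27e-05; adjusted p = 0.668 with an estimated correlation), 9 members with an unadjusted p under 0.05 by limma, 4 when adjusted over the list alone and 0 over all genes. Mbp was at 537.5 ± 175 TPM in scrambled and 191 ± 50.9 TPM in knockdown long tails. Sterol synthesis genes (20 of 24 higher, median 0.28, adjusted p = 5.42e-06), proteasome subunits (30 of 32, median 0.18, adjusted p = 5.42e-06) and ribosomal proteins (67 of 80, median 0.11, adjusted p = 3.8e-05) were called upward. Translation factors (median 0.03, adjusted p = 0.0238), oxidative phosphorylation subunits (0.03, adjusted p = 0.0492) and dendritically localised mRNAs (median 0.00, mean −0.02, adjusted p = 0.0456) were called upward relative to an all-gene median of −0.10. These 6 lists had an adjusted p of 0.981 with an estimated correlation, fry called 0 lists, and each had 0 members when adjusted over the list alone. The sterol and dendritic calls ended without knockdown long-tail library 1. The proteasome, ribosomal, translation and oxidative phosphorylation calls ended without library 2 of that group, the library that stood apart. The dendritic call ended without scrambled long-tail library 2, the translation and oxidative phosphorylation calls without scrambled long-tail library 1, and the oxidative phosphorylation call without any of the 4 total libraries. The translation, oxidative phosphorylation and dendritic calls also ended with quantile normalization or at a mean of 20 TPM, and the ribosomal call with quantile normalization.

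**Figure D2:**
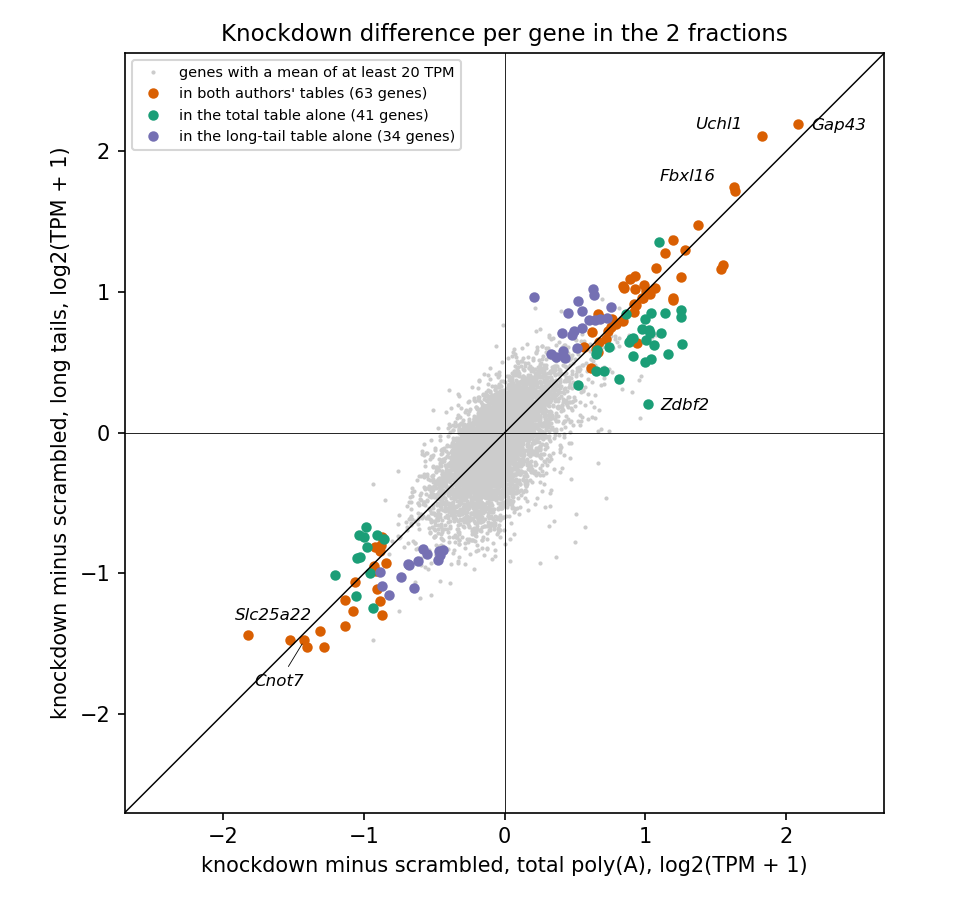
Knockdown minus scrambled difference in log2(TPM + 1) in total RNA (horizontal axis) and in long tails (vertical axis) for genes with a mean of at least 20 TPM (grey), with genes of both of the authors' tables in orange (63), of the total table alone in green (41) and of the long-tail table alone in purple (34); the line is the diagonal. All 138 genes of the tables, which were chosen on these libraries, had the same sign in both fractions, against 74.6% of genes with a mean of at least 20 TPM.

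Whether the knockdown acted differently on the long-tail fraction was asked with the overlap of the tables and with the interaction. The authors' deposited tables share 63 genes, 43 higher and 20 lower in both and 0 in opposite directions, where 0.332 and 0.0795 were expected for independent tables (odds ratio 596). The labels do not exclude that both fractions came from the same cultures, in which case chance differences between cultures would also give an overlap and shared signs. All 138 genes of either table had the same sign in both fractions in TPM, against 72.8% of all tested genes with a difference in both fractions. They were chosen on these same libraries, so part of this was fixed in advance. The interaction of these 138 genes had a median size of 0.188 and was largest for Zdbf2 (0.815), with 95% confidence limits at a median distance of 0.644 on either side. By limma, 0 of the 138 passed over all genes or over the set alone, and 1 had an unadjusted p under 0.05. Over all tested genes limma called 0 (smallest adjusted p = 0.522), 120 had an unadjusted p under 0.05, 54 upward and 66 downward, and no filter or scaling gave a call. By chance 684.05 were expected, more than were found, so 0 calls do not exclude differences between the fractions. The 10 genes with the smallest p (among them Cd248, Gm6277 and Casp1) were at 3.5 TPM or less in every group. For Cnot7 the interaction was −0.05. Across genes with a mean of at least 20 TPM the knockdown differences of the 2 fractions correlated at r = 0.704, though genes are not independent replicates.

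Camera called 4 of 26 lists in the interaction, and all 4 had an adjusted p of 1.00 with an estimated correlation. Replication-dependent histones were lower (47 of 53 members, median −0.84, adjusted p = 5.7e-06), Hist1h2bj for example at 4 ± 1.41, 8 ± 2.83, 7 ± 2.83 and 3 ± 2.83 TPM in scrambled total, knockdown total, scrambled long and knockdown long. RNA granule proteins were lower (37 of 45, median −0.12, adjusted p = 0.0268). Oxidative phosphorylation subunits were higher (61 of 77, median 0.11, adjusted p = 0.00108), and ribosomal proteins were higher (54 of 80, median 0.05, adjusted p = 0.0268). By fry 0 were called, and 0 members of each passed over the list alone. Without knockdown long-tail library 2 or without knockdown total library 2 the histone, oxidative phosphorylation and ribosomal calls ended; the histone list had a median of −1.42 in the first library and 1.24 in the second, and between −0.39 and 0.21 in the other 6. The histone and ribosomal calls also ended without scrambled long-tail library 1, the ribosomal call without scrambled total library 2, and the granule call without scrambled total library 1, scrambled long-tail library 2, knockdown total library 1 or 2, or knockdown long-tail library 2. The histone call ended at a mean of 20 TPM, and the ribosomal and oxidative phosphorylation calls with quantile normalization.

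Between long-tail and total libraries camera called lists of short housekeeping mRNAs higher and of neuronal receptor and channel mRNAs lower, relative to other genes. With an estimated correlation these lists had an adjusted p of 0.759 in scrambled and 0.978 in knockdown neurons, and fry called 0 lists. Bc1, a short RNA polymerase III transcript of neurons that is carried into dendrites and has an A-rich stretch inside, was at 1240.5 ± 663 TPM in scrambled total RNA and 108 ± 36.8 TPM in scrambled long tails. In knockdown it was at 1038 ± 280 and 76.5 ± 14.8 TPM. Subunits of oxidative phosphorylation were higher in long tails of scrambled neurons in 70 of 77 (median 0.21, adjusted p = 9.07e-22), Ndufc1 of complex I for example at 286 ± 7.07 TPM in total RNA and 415.5 ± 23.3 TPM in long tails, and ribosomal proteins in 72 of 80 (median 0.14, adjusted p = 6.43e-17). Voltage-gated channels were lower in 54 of 55 (median −0.45, adjusted p = 0.00186) and glutamate receptors in 31 of 32 (median −0.44, adjusted p = 0.00882), among them Neto1, an auxiliary subunit of glutamate receptors (49.5 ± 0.707 and 32.5 ± 3.54 TPM). Above the median of all genes were 6 of 55 channels and 4 of 32 glutamate receptors.

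The median over all genes was −0.22 in both comparisons of fractions as deposited, and −0.01 and −0.03 after median scaling. Camera calls are relative to other genes, while the list medians and the counts of higher or lower members are in TPM as deposited. Camera called 12 of 26 lists in scrambled neurons, 7 higher and 5 lower. Beside those above, proteasome subunits were higher (median 0.05, adjusted p = 6.31e-06), and poly(A) factors (32 of 36 lower, median −0.39, adjusted p = 0.00107), dendritically localised mRNAs (46 of 50, −0.39, adjusted p = 0.00438) and presynaptic genes (48 of 50, −0.35, adjusted p = 0.0275) were lower. Above the median of all genes were 8 of 36 poly(A) factors, 10 of 50 dendritic mRNAs and 15 of 50 presynaptic genes. The smallest adjusted p of the 12 lists with an estimated correlation was 0.759. Histones (median −0.05, adjusted p = 0.00035), inhibitory neuron markers (−0.13, adjusted p = 0.0275), microglia markers (0.00, adjusted p = 0.0275) and interferon-stimulated genes (−0.08, adjusted p = 0.025) were called upward only relative to the lower median of all genes, and these 4 calls ended with median scaling or quantile normalization and without scrambled long-tail library 1 (library 2 for the interferon list). The channel, glutamate receptor, dendritic and presynaptic calls ended without scrambled total library 1 or without scrambled long-tail library 2. Adjusted over the list alone, 1 member of the dendritic list (Bc1) and 0 members of the other 11 passed.

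In knockdown neurons camera called 11 of 26 lists, 5 higher and 6 lower. Oxidative phosphorylation subunits (72 of 77 higher, median 0.35, adjusted p = 5.26e-22), ribosomal proteins (75 of 80, 0.20, adjusted p = 4.65e-16) and proteasome subunits (24 of 32, 0.12, adjusted p = 3.29e-05) were higher. Channels (53 of 55 lower, median −0.67, adjusted p = 0.000649), poly(A) factors (34 of 36, −0.45, adjusted p = 0.000649), RNA granule proteins (40 of 45, −0.53, adjusted p = 0.00681), GABA receptors (15 of 17, −0.55, adjusted p = 0.0226), dendritically localised mRNAs (44 of 50, −0.32, adjusted p = 0.0395) and glutamate receptors (28 of 32, −0.62, adjusted p = 0.0453) were lower. These counts are in TPM as deposited. Above the median of all genes were 10 of 55, 7 of 36, 13 of 45, 2 of 17, 16 of 50 and 6 of 32 members, in the same order. The smallest adjusted p of the 11 lists with an estimated correlation was 0.978. Gabra2 was at 130.5 ± 13.4 TPM in total RNA and 66.5 ± 17.7 TPM in long tails, and the AMPA receptor subunit Gria2 at 177.5 ± 24.7 and 83 ± 31.1 TPM. The poly(A) polymerase Papola was at 76.5 ± 2.12 and 47 ± 5.66 TPM, and the splicing regulator Mbnl1 at 25 ± 2.83 and 11.5 ± 3.54 TPM. Adjusted over the list alone, 9 poly(A) factors, 13 granule proteins, 3 GABA receptors, 3 glutamate receptors and 1 dendritic RNA (Bc1) passed, against 0 over all genes. Microglia markers (median 0.21, adjusted p = 0.018) and interferon-stimulated genes (median 0.00, mean −0.11, adjusted p = 0.0289) were called upward, and both calls ended with median scaling. Without knockdown long-tail library 2, which stood apart, 6 lists were called, and the channel, proteasome, GABA receptor, glutamate receptor, dendritic and interferon calls ended. Relative to each gene's mean, ribosomal medians were 0.0229 and −0.158 in knockdown total and −0.186 and 0.443 in knockdown long-tail libraries 1 and 2. Those of oxidative phosphorylation were −0.0855 and −0.287, and −0.144 and 0.452, in the same order. In TPM as deposited, long-tail library 1 was thus not above both total libraries for either list. The GABA receptor call also ended without knockdown total library 2, and the microglia call without knockdown long-tail library 1. The dendritic and interferon calls ended without knockdown total library 1, and the dendritic call without either scrambled long-tail library. The glutamate receptor call ended without any of 5 further libraries (knockdown total library 1 and the 4 scrambled libraries), and the ribosomal call with quantile normalization.

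Gene by gene, limma called 0 genes in either comparison of fractions (smallest adjusted p = 0.0746 in scrambled and 0.105 in knockdown neurons). In scrambled neurons 1800 genes had an unadjusted p under 0.05, 36 higher and 1764 lower in long tails, and in knockdown neurons 3562, 126 higher and 3436 lower, in TPM as deposited with its median of −0.22. Libraries did not overlap for 44.28% and 44.05% of genes, against 33.3% by chance for values without ties, a share that ties lower. At a mean of 5 TPM Bc1 and Lrrc17 were called in scrambled neurons, the latter named after its values were seen, and without a filter 33 and 56 genes were called in the 2 comparisons. With a filter and the replicate number as a block, far more genes were called in knockdown neurons, as given below, though the labels state no pairing. Leaving out single libraries also changed these counts, as given below. Without knockdown long-tail library 1 the knockdown comparison rested on long-tail library 2 alone, which stood apart. Bc1 had an adjusted p of 0.178 in scrambled and 0.125 in knockdown neurons. The genes with the smallest p were at 17 TPM or less in every group (Snhg10, Resp18, Barx2 and Cd248 upward and Alpk1 and Pde7b downward, for example). Across genes with a mean of at least 20 TPM, the long-tail minus total differences of scrambled and knockdown neurons correlated at r = 0.87.

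**Figure D3:**
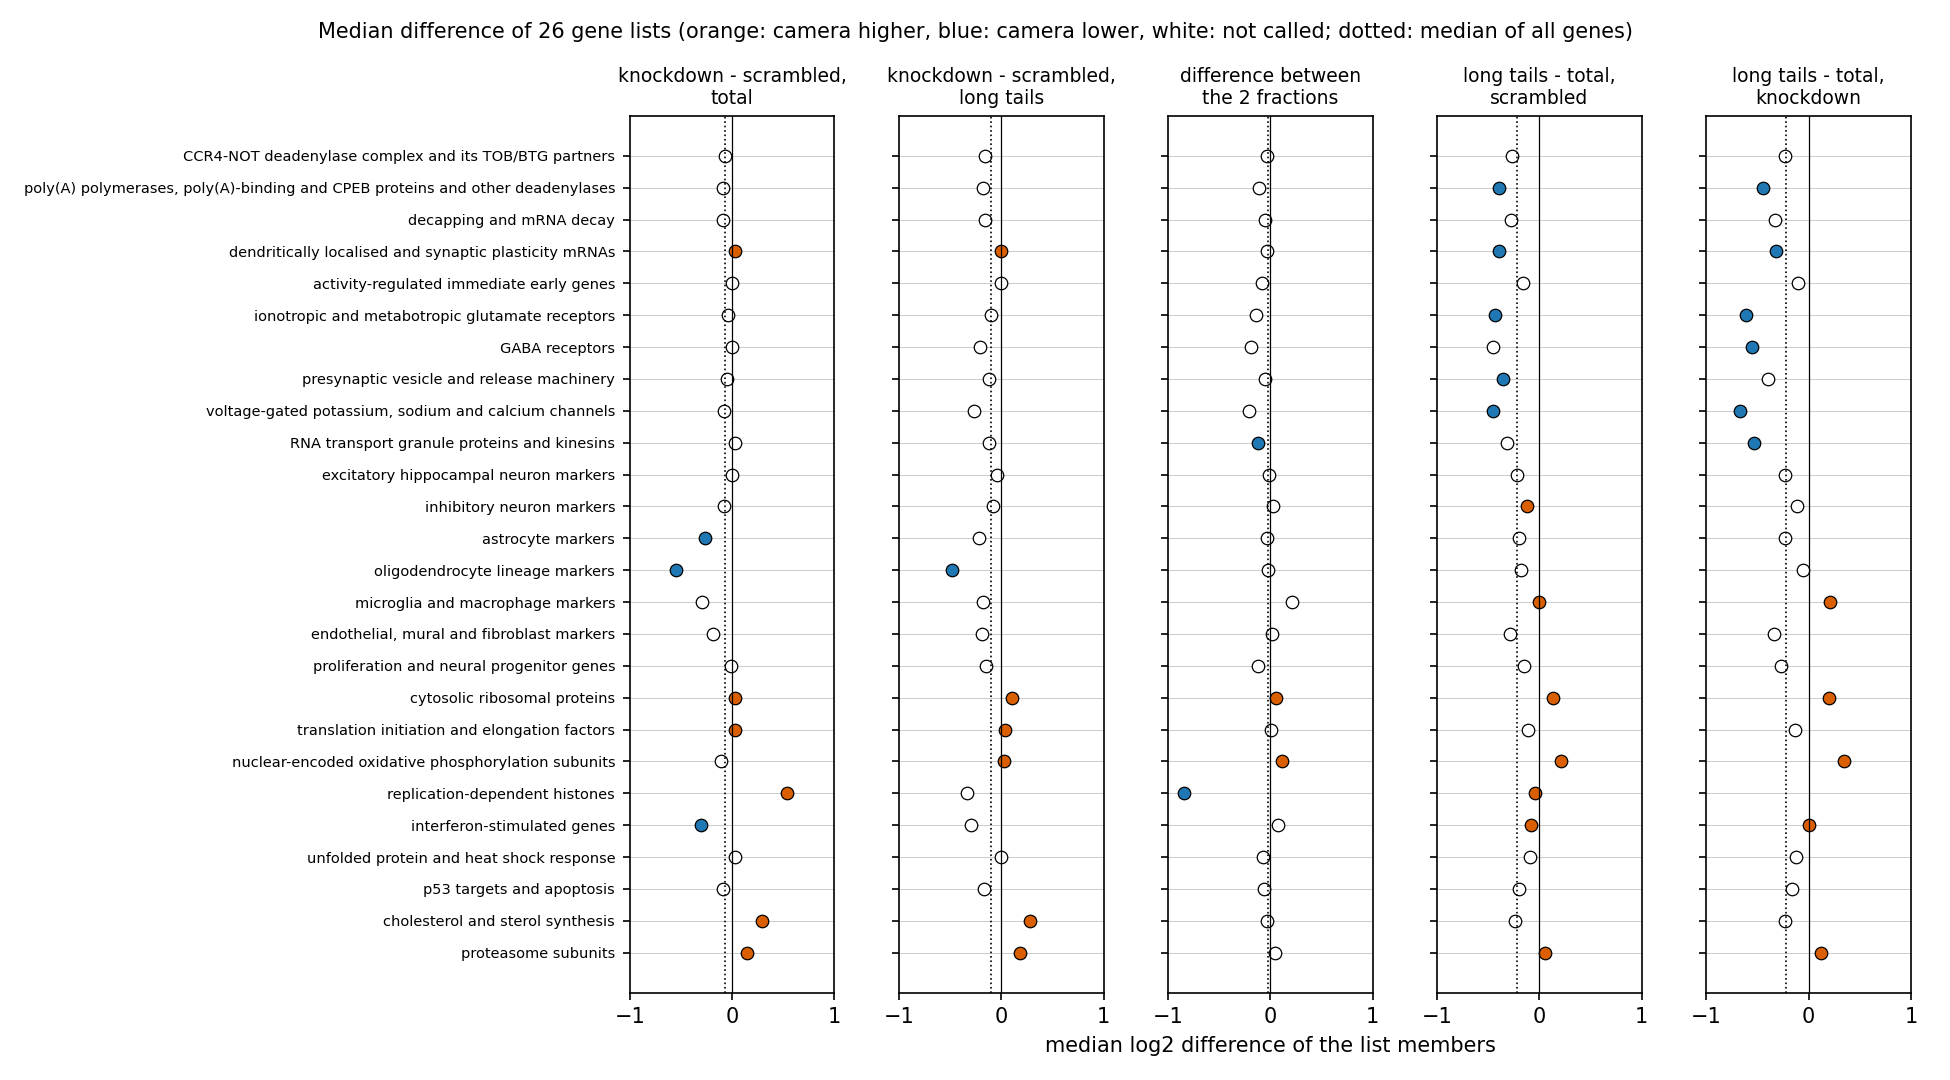
Median log2 difference (horizontal axes) of 26 gene lists in the 5 comparisons, with lists called higher by camera in orange, called lower in blue and not called in white; the dotted line is the median of all genes. Oligodendrocyte markers were at −0.55 in total RNA and −0.48 in long tails.

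Transcript length went with the difference between an mRNA's share of the long-tail and of the total libraries. In the shortest of 20 bins of genes, at a median length of 551 nucleotides, the median long-tail minus total difference was 0.00 in scrambled and 0.10 in knockdown neurons, and in the longest, at 7621 nucleotides, it was −0.54 and −0.84. The Spearman correlation across 13080 genes was −0.568 in scrambled and −0.588 in knockdown neurons, and between −0.604 and −0.289 for every pair of a long-tail and a total library of knockdown neurons. Pairs with knockdown long-tail library 2, which stood apart, were at −0.564 and −0.604, and pairs with library 1 at −0.289 and −0.376. Scrambled pairs ran from −0.545 to −0.376, so a stronger relation with length after knockdown is not shown. Genes are not independent replicates, and the lists above differ in length.

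**Figure D4:**
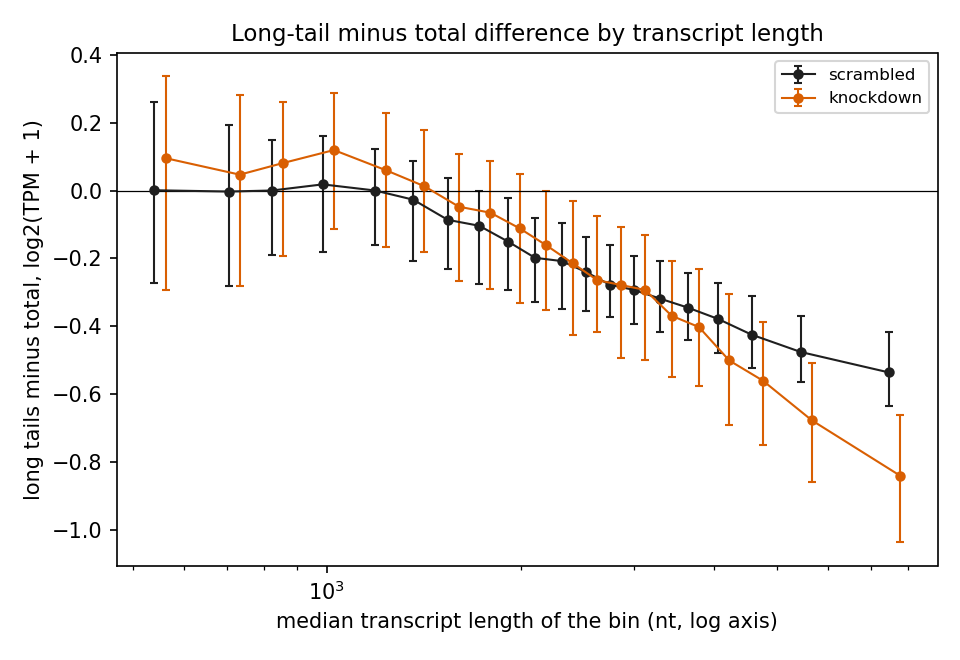
Long-tail minus total difference in log2(TPM + 1) (vertical axis) by median transcript length in nucleotides (horizontal axis, log scale) in 20 bins of 654 genes, as medians (points) with quartiles (bars) in scrambled (black) and knockdown (orange) neurons. In scrambled neurons the median went from 0.00 in the shortest to −0.54 in the longest bin.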

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

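The tests of transcript length, of a single deviating library and of chance differences below were chosen only after the patterns had been seen. The knockdown difference between fractions, tested as an interaction, passed for 4 lists and is therefore given here: replication-dependent histones (adjusted p = 5.7e-06), oxidative phosphorylation subunits (adjusted p = 0.00108), ribosomal proteins (adjusted p = 0.0268) and RNA granule proteins (adjusted p = 0.0268), each with an adjusted p of 1.00 when the correlation between genes was estimated. Histone mRNAs of this class end in a stem-loop and mostly lack a poly(A) tail, and their medians were 1.24 in knockdown total library 2 and −1.42 in knockdown long-tail library 2.

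By camera, lists of short housekeeping mRNAs were called higher, and lists of channel and receptor mRNAs lower, in long-tail than in total libraries. With an estimated correlation these lists had an adjusted p of 0.759 in scrambled and 0.978 in knockdown neurons. A length bias between libraries was tested as the whole source by drawing 10000 random lists matched on transcript length: 3 of 3 lists lay outside the central 95% of these, oxidative phosphorylation at 0.291 against −0.0929 to 0.0933, ribosomal proteins at 0.176 against −0.0777 to 0.106, and channels at −0.577 against −0.510 to −0.337. The random lists held unrelated genes and were not matched on expression level. A list whose genes vary together can lie outside them without another source, so the test cannot decide whether length was the whole source. The length-matched median for channels, −0.419, covered most of their difference. Those for oxidative phosphorylation (0, against 0.291) and ribosomal proteins (0.0184, against 0.176) covered little of theirs. That the deviating knockdown long-tail library made the relation was argued against by the scrambled libraries alone, in which the Spearman correlation with length was −0.568, from −0.545 to −0.376 over their library pairs. Length as the whole source thus stays open. It also stays open that shorter mRNAs may carry longer tails in these neurons or that the wash may act on RNA by more than its tail, neither of which was tested.

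Knockdown differences ran parallel in the 2 fractions. Chance differences between cultures carried into both fractions were tested by correlating the difference in total libraries of one number with that in long-tail libraries of the other, which gave 0.553 and 0.729, a mean of 0.641, with −0.0793 to 0.781 over the 16 combinations. Because the labels do not say that the 2 libraries of a group came from separate cultures, this source and an effect of the knockdown cannot be told apart for these libraries.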

How the results depend on the processing

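Filters at means of 10, 20 and 50 TPM, each alone, with median scaling and with the replicate block, and the table without Rn45s were chosen after seeing the data; the other alternatives were planned. The planned result was 0 genes in each of the 5 comparisons by limma, and the counts below show how far that number depended on low genes; the cause was not tested unless stated. In the order total RNA, long tails, fractions in scrambled and fractions in knockdown neurons, the counts were 43, 54, 33 and 56 without a filter, 6, 5, 2 and 1 at a mean of 5 TPM, 10, 11, 2 and 2 at 10 TPM, 7, 13, 1 and 1 at 20 TPM, and 8, 12, 1 and 1 at 50 TPM. Fitting only the 4 libraries compared gave 50, 83, 87 and 97, and 0 of the 50 and 83 are in the authors' tables. In total RNA and long tails, median scaling gave 1 and 1 (Gap43), quantile normalization 4 and 1 (Cdkl2, Gap43, Klc1 and Slc25a22, and Gap43), leaving out Rn45s 1 and 1 (Gap43), and median scaling with a filter gave 3 and 1 at 5 TPM, 4 and 1 at 10 TPM, 3 and 1 at 20 TPM (each with Gap43 and Slc25a22 in total RNA, and Gap43 in long tails) and 11 and 7 at 50 TPM. The fraction calls at 5 to 50 TPM were of Bc1 and Lrrc17. The interaction stayed at 0 under every alternative run. Pseudocounts of 0.1 and 5 and a fit without trend gave 0 genes in all 5 comparisons.

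Whether the replicate number pairs the libraries was left open, as the labels do not state a pairing. Library deviations from their group means correlated across genes at −0.108 for knockdown total with knockdown long tails and at 0.218 to 0.605 for the other 5 pairs of groups. The second principal component (20.4% of variance) separated the libraries of number 1 from those of number 2 in all 4 groups, a hint from the data of structure shared by number. With the number as a block, 0 genes were called in all 5 comparisons at a mean of 1 TPM. With a filter the blocked counts, in the order above, were 19, 29, 2 and 1738 at 5 TPM, 91, 121, 6 and 2046 at 10 TPM, 118, 297, 99 and 1451 at 20 TPM, and 67, 109, 14 and 449 at 50 TPM.

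Leaving out 1 library at a time gave 0 to 1 genes in total RNA (Spata9, without scrambled total library 2), 0 to 2 in long tails (4833419F23Rik and Lrrc18, without knockdown long-tail library 2), 0 in the interaction, 0 to 57 for fractions in scrambled neurons (57, 56 and 41 without knockdown total library 1, knockdown total library 2 and knockdown long-tail library 2) and 0 to 2125 for fractions in knockdown neurons (2125 without knockdown long-tail library 1, 12 without knockdown total library 1). A group left with 1 library was assumed to vary like the others. Without knockdown long-tail library 1 that group held only library 2, which stood apart, so the calls there may reflect that library.

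Cnot7 was lower in knockdown under every alternative run, at log2 −1.62 to −1.22 in total RNA and −1.61 to −1.20 in long tails. It passed at a mean of 10 TPM (−1.42 and −1.48; adjusted p by limma = 0.0299 and 0.024) and of 20 TPM (adjusted p = 0.0253 and 0.0154), and with the block at 5, 10 and 20 TPM (adjusted p = 0.0144 and 0.0136, 0.000336 and 0.000234, 2.28e-07 and 3.9e-08), against ranges of 2.28e-07 to 0.512 and 3.9e-08 to 0.605 over all alternatives.

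Lists called by camera numbered 9 in total RNA, 7 in long tails, 4 in the interaction, and 12 and 11 for fractions in scrambled and knockdown neurons. With an estimated correlation or with fry 0 were called in all 5. At a mean of 20 TPM 4 were called in long tails, and with quantile normalization 2 in the interaction. Leaving out 1 library gave 2 to 10 lists in total RNA (2 without knockdown total library 1), 6 to 12 in long tails, 2 to 11 in the interaction (2 without knockdown total library 2, 11 without knockdown long-tail library 1), 9 to 13 for fractions in scrambled and 6 to 12 in knockdown neurons. The oligodendrocyte list was called lower in total RNA and long tails in all 7 settings and all 8 left-out libraries at the preset correlation.

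The odds ratio of the overlap between the authors' tables was 596, 1080 with all genes as background, 498 with genes of at least 5 TPM and 1180 at an adjusted p of 0.01 in their tables.

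For the genes of the rule that are reported, 235 pairs of gene and comparison gave 5877 recomputed values, of which 5526 kept their side of the threshold (2 of these, for Tyrobp and Laptm5, fell to 0), 345 passed it and 6 turned in sign. Among these the sign turned only for microglia markers, and only with a library left out. With a library left out, scrambled fractions ran from −1.5 to 0.8219 for C1qa, −0.5 to 0.8219 for Fcer1g and −0.5 to 1.5 for Tyrobp, and knockdown fractions from −0.161 to 0.839 for Lyz2. Depth is unknown, so its limit on these values could not be given.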

Other observations

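The genes named in this paragraph were chosen after their values were seen, apart from Bc1. Among 6810 genes with a mean of at least 20 TPM, Bc1 had the largest fall in share from total to long-tail libraries (mean log2 −3.59 over both conditions, lower in 8 of 8 pairs of a long-tail and a total library of the same condition). It was followed by Cdr1 (−1.83, 8 of 8 pairs), at 240.5 ± 31.8 TPM in scrambled total and 67 ± 28.3 TPM in scrambled long-tail libraries, and the long non-coding RNA Ipw was among the 10 lowest (−1.43, 8 of 8 pairs). Lrrc17, with a lower mean, was at 33.5 TPM in scrambled total and 4 TPM in scrambled long-tail libraries, and at 33 and 5.5 TPM in knockdown. At the other end stood Snhg3, a host transcript of small nucleolar RNAs (0.76, higher in 8 of 8 pairs), and Gng13, a G protein gamma subunit (0.64, higher in 8 of 8). In TPM as deposited, where the median over all genes was −0.22, 2268 of these genes were lower and 160 higher in long tails in all 8 pairs. After median scaling 1364 were lower and 1265 higher.

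Mtmr7 lies close to Cnot7 on the minus strand of chromosome 8 (40551095 to 40634797), upstream of it on that strand. It was at 8.50 ± 0.707 TPM in scrambled and 27 ± 4.24 TPM in knockdown total RNA, and at 8 ± 1.41 and 19.5 ± 0.707 TPM in long tails, the direction opposite to Cnot7. Its position was looked at after its values were seen, and no explanation was tested.

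Oligodendrocyte lineage markers were lower in knockdown neurons in both fractions, and the tests of this pattern were chosen only after it had been seen. With an estimated correlation the list had an adjusted p of 0.284 in total RNA and an adjusted p of 0.668 in long tails, so its call was lost in both. Fewer cells of the lineage as a whole would lower all its markers alike. The 6 genes taken as precursor markers for the test (Pdgfra, Cspg4, Olig1, Olig2, Sox10 and Gpr17) were not shown to be limited to precursors. They had a median of −0.17 and 8 myelin markers one of −0.97 in total RNA, a difference of 0.80 (permutation p = 0.00999 over 3003 splits, two-sided). The sets overlapped: Sox10 (−0.50) and Gpr17 (−0.55) fell more than the myelin markers Mag (−0.33) and Mal (−0.24). The permutation measures spread between marker genes, which are not independent, and not between cultures. The medians were thus not alike in these libraries, but fewer cells of the lineage as a whole are not excluded. Rounding of low values was argued against by the 17 members with a mean of at least 5 TPM, whose median was −0.50 (bootstrap 95% interval −0.691 to −0.180, 16 of 17 lower, its upper end short of the bound of −0.2 set for the test); with every value moved by 0.5 TPM against the difference, a bound added after the first result, the median over 23 members was still −0.243. Other non-neuronal markers were also lower in total RNA: astrocyte (26 of 29, median −0.26, adjusted p = 0.0236; adjusted p = 0.973 with an estimated correlation), and, not called, microglia (9 of 11, −0.29) and endothelial and mural (22 of 26, −0.19). In long tails none of these 3 was called, with 26 of 29 astrocyte (median −0.22, adjusted p = 0.074), 9 of 11 microglia (−0.18) and 21 of 26 endothelial and mural markers lower (−0.18). In total RNA the microglia medians per library overlapped between scrambled (0.512 and −0.219) and knockdown (0.0212 and −0.472). So did the endothelial and mural medians (0.126 and 0.428, against −0.113 and 0.274). The median over all genes there was −0.07. Open candidate explanations are fewer cells of the lineage as a whole, a loss of mature cells, a wider change in the share of non-neuronal cells, or a change in myelin gene expression after knockdown. These libraries do not separate them.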
